A study of Mus musculus with 9 samples.

How the data were processed

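Single cells of mouse pancreas were profiled by droplet-based 10x sequencing in 9 samples: 2 of normal Msi2-GFP cells, 3 of pre-cancer pancreas from Msi2CreER-MycT58A mice 5 weeks after tamoxifen induction, and 4 of tumours of that model at 12 weeks (1 labelled ACC, 1 ASCP and 2 Mixed). Per the labels, induction was at 8 weeks of age. The deposited files hold raw UMI counts per gene and barcode, 1 matrix per sample, with 31053 genes and 6794880 barcodes each, unfiltered and not normalised. Per the submitters' processing notes, Cell Ranger 3.0, Seurat 3.0 and the mouse genome build mm10 were used. No reporter or recombinase gene is among the features, so counts from the MycT58A transgene and from endogenous Myc cannot be separated.

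Cells were called from each matrix. A barcode counted as a cell where its UMIs reached 10% of the 99th percentile of the top 3000 barcodes, or where it held 500 or more UMIs and differed from the ambient profile (barcodes ranked from 45000 to 90000 by UMIs) in a Monte Carlo test with 10000 draws at a false discovery rate of 0.01. Cells then needed at least 500 UMIs and 300 genes and at most 20% mitochondrial UMIs. Doublets were scored per sample with Scrublet as implemented in scanpy 1.11.5, and the highest-scoring 0.8% per 1000 called cells were left out. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering (leidenalg 0.10.2, resolution 1.0) were used on all samples together, without batch integration. The 32 clusters were named by marker lists, with "like" marking that the names rest on markers alone. A cluster of normal cells led by enzyme genes at low UMI counts was kept out of the acinar-like class after its values were seen. Exocrine epithelial cells are the acinar-like, ductal-like, squamous-like, tuft-like and unnamed epithelial clusters pooled. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0, and R 4.3.3.

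For each comparison, raw counts were summed per sample within the cell class, for samples with at least 20 cells, so that the sample and not the cell is the replicate. edgeR 4.0.16 was used with filterByExpr, TMM scaling, estimateDisp, robust quasi-likelihood fits and the quasi-likelihood F-test, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Pre-cancer against normal used the group as a factor with 5 levels, and tumours against pre-cancer used the week (0, 5 and 12) as a factor, so that the 12-week level pools the 4 tumours and differences between tumour types are part of its spread. Values per gene are TMM-scaled CPM (UMIs relative to the scaled library size), computed within each comparison, and changes are log2 fold changes with their standard error. Of 9 planned comparisons 4 were run. Those in ductal-like, macrophage-like, fibroblast-like and T cell-like cells were left out because fewer than 2 samples on a side held 20 such cells.

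Gene lists were tested with camera (limma 3.58.1) with an inter-gene correlation of 0.01 on log-CPM with a prior count of 2, adjusted over the lists of a comparison. The test was repeated with the correlation estimated from the data, and fry was run beside it. There were 23 lists, each named beside its result, of which markers of immune, stromal, endocrine, erythroid and acinar cells serve as signs of other cells. The acinar marker list is a subset of the digestive enzymes, and the trypsin genes in both are near-identical paralogs.

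Genes are named in the text by rule. Msi2 and Myc are always given. From each list, up to 3 members that passed the test with the largest absolute change are named, or, where none passed, the 2 members with the highest mean CPM as values. In each comparison the 6 genes up and the 6 down with the largest change are added among those that passed, with a mean CPM of at least 50 and no overlap between the replicates of the sides, leaving out Gm, Rik, LOC, AC and mitochondrial names. Between the ACC and ASCP tumours the 10 genes higher in each by the ratio of CPM + 10 are named, at a CPM of at least 100 in one of them. Genes that lead a cluster were named after their values were seen.

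Where all samples of a side held 0 counts, the fold change is given only as a lower bound against a floor of 3 counts over the group. With 1 to 3 counts on a side it is a ratio of pooled CPM with an exact 95% counting interval. Shares of cells carry exact 95% Clopper-Pearson intervals, and list sums exact Poisson intervals. All of these cover counting error only. Shares were compared between groups with exact two-sided permutation tests, adjusted over the 14 classes of each step. Depth ran from 7680243 to 58280304 UMIs per sample.

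The groups, comparisons, tests, lists, the naming rule and most alternatives were fixed before the data were examined. The alternatives were DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, no filter on low counts, each replicate left out in turn, at most 10% mitochondrial UMIs, at least 1000 UMIs, doublets kept, naming each cell by its own marker score, at least 50 cells per sample, subtraction of ambient RNA, digestive enzyme genes left out, counts thinned to the smallest sample, only the samples of the 2 sides, only the Mixed tumours as the 12-week side, and a replicate block from the replicate numbers in the labels. Chosen after seeing the data were keeping only cells that differ from the ambient profile, counting the low-UMI enzyme cluster as acinar-like, leaving a cluster led by ciliary genes out of the ductal-like share, and total UMIs, with or without enzyme genes, as the scale.

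The pipeline was tested on simulated data with 200 changed genes and 1 dispersion, each fit's median. Of genes changed 4-fold, 98% and 90% were recovered for pre-cancer against normal in acinar-like and exocrine epithelial cells, and 94% and 78% for tumours against pre-cancer. Of genes changed 2-fold, 42%, 14%, 46% and 10% were, in the same order. False calls were 3.9% to 6.8% of calls. Rates on real data may differ.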

Results

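The data are UMI counts of single cells from mouse pancreas at 3 stages: Msi2-GFP cells of normal pancreas (n = 2), pre-cancer pancreas at 5 weeks (n = 3) and tumours at 12 weeks after induction (n = 4: 1 ACC, 1 ASCP and 2 Mixed). Msi2 encodes the RNA-binding protein Musashi 2. In the Msi2CreER-MycT58A model, tamoxifen activates a Cre recombinase driven by Msi2, which switches on a stabilised mutant of the transcription factor MYC. The normal samples come from a different mouse line, are labelled as reporter-positive cells and were taken at 0 weeks, so line, time and labelled sorting differ together between normal and all other samples. After filters 2008 and 5366 normal cells, 4126, 3812 and 6542 pre-cancer cells, and 2024 ACC, 702 ASCP and 2416 and 2426 Mixed cells remained. The share that differed from the ambient profile was lowest in pre-cancer samples 2 and 3 and the ACC tumour (2112 of 3936, 2629 of 6926 and 1326 of 2058, doublets included). Median UMIs per cell were 5395.5 and 6165.5 in the normal samples and 2237.5, 3270.0 and 1903 in the pre-cancer samples. They were 1165.5 in the ACC, 1958.5 in the ASCP, and 11380.0 and 2700.0 in the Mixed tumours.

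The first question was which cells each stage held. With cells named by cluster, normal samples were mostly ductal-like cells, pre-cancer samples almost wholly acinar-like cells, and the tumours differed from one another. Acinar-like cells, named by acinar markers, were 12.1% (95% interval 10.7 to 13.6) and 5.74% (5.13 to 6.40) of normal cells, and 98.1%, 98.4% and 99.2% of pre-cancer cells. They were 81.7% (79.9 to 83.3) of the ACC, 10.4% (8.24 to 12.9) of the ASCP, and 21.1% (19.5 to 22.7) and 18.8% (17.3 to 20.5) of the Mixed tumours. Ductal-like cells were 66.2% and 52.7% of normal cells, among them 227 and 48 cells of a cluster led by Foxj1 and other ciliary genes, without which they were 54.9% and 51.8%. In pre-cancer sample 1 they were 0 of 4126 cells, which allows a share of up to 0.0727%, and in the other pre-cancer samples 2 and 1 cells. Endocrine-like cells were 19.2% and 4.25% of normal cells. Unnamed epithelial cells were 69.2% (65.7 to 72.6) of the ASCP tumour and 7.70% and 61.4% of the Mixed tumours. Squamous-like cells, with keratins of stratified epithelium such as Krt5 and Krt14, were 9.69% (7.60 to 12.1, 68 cells) of the ASCP tumour and 0.621% and 0.330% of the Mixed tumours. Macrophage-like cells were 6.47% (5.44 to 7.63) of the ACC tumour and 44.2% (42.3 to 46.3) of Mixed tumour 1. These intervals cover counting error only.

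The acinar-like share was 98.5% ± 0.546 (SD, n = 3) in pre-cancer and 8.92% ± 4.50 (n = 2) in normal samples, a difference of 89.6 percentage points. Its exact two-sided permutation p was 0.2, the smallest that 3 against 2 samples allow (adjusted p = 0.311). The ductal-like share was 0.0226% ± 0.027 against 59.5% ± 9.51, with the same exact p. In the tumours the acinar-like share was 33.0% ± 32.8 (n = 4), a change of -65.6 points from pre-cancer, and the macrophage-like share 12.8% ± 21.2, a change of 12.7 points, which was 2.25 without Mixed tumour 1. Both main changes were at the smallest exact permutation p that 4 against 3 samples allow, 0.0571 (adjusted p = 0.267). The unnamed epithelial share, 34.6% ± 35.8 in the tumours, had an exact permutation p of 0.229 (adjusted p = 0.32), and no share passed the threshold. Squamous-like cells, 2.66 points up in the tumours and 0.317 without the ASCP tumour, had the same exact p. These shares depend on how cells are named. A low-UMI cluster led by enzyme genes, 0.896% and 35.8% of normal samples 1 and 2, was left unnamed after its values were seen. Counted as acinar-like, it puts their shares at 13% and 41.6%, and the difference from pre-cancer at 71.3 points. Naming each cell by its own marker score gave acinar-like shares of 44.2% in pre-cancer and 17.6% in normal samples, 26.6 points apart. The change in the tumours was -38.4 points. The ductal-like difference between pre-cancer and normal was then -31.0 points, and 12.4% of pre-cancer cells were named NK-like, 7.18% T cell-like and 7.57% plasma cell-like.

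**Figure D1:**
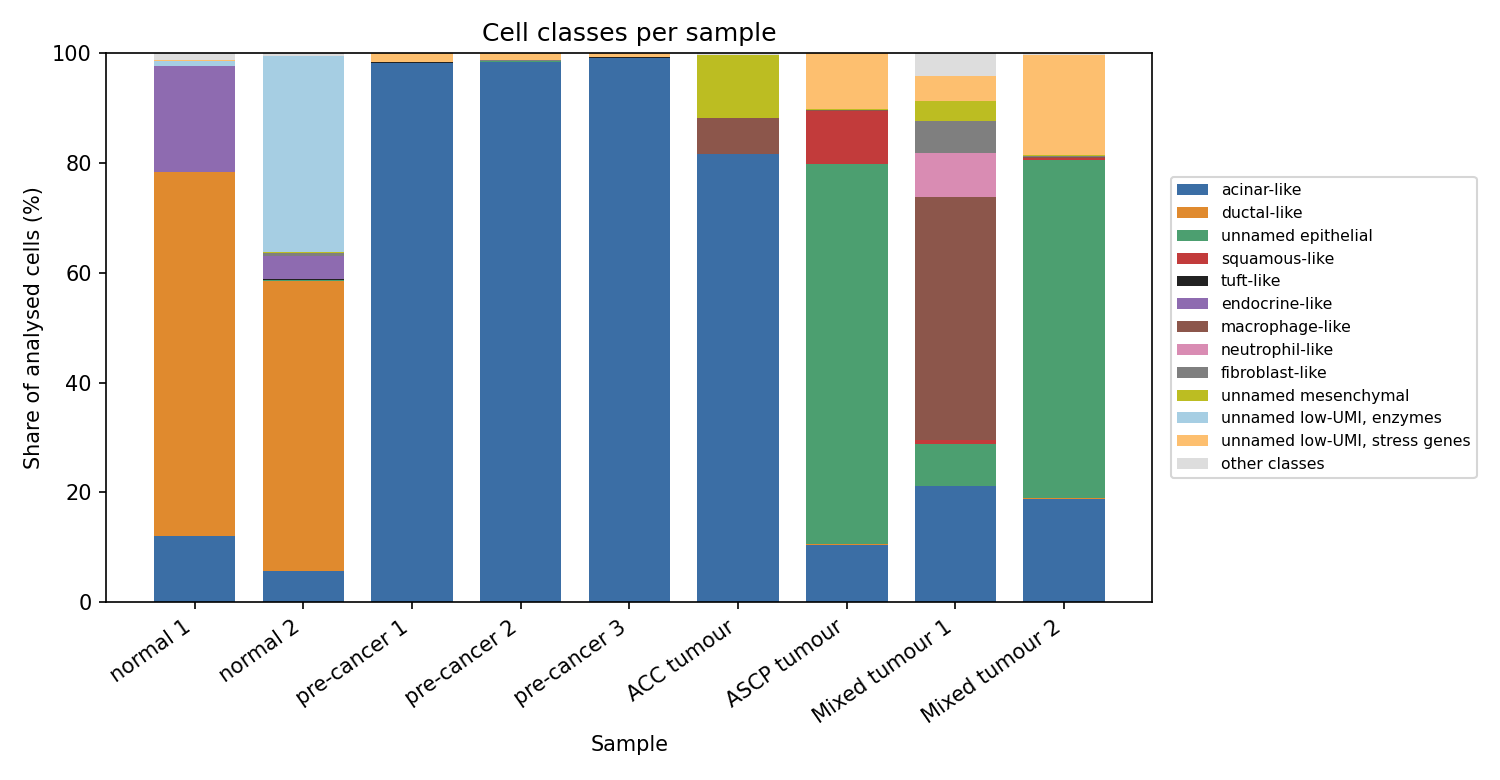
Share of analysed cells (percent, vertical axis) in each cell class for the 9 samples, 1 stacked bar per sample. Acinar-like cells fill over 98% of each pre-cancer bar, 81.7% of the ACC bar and 10.4% of the ASCP bar.

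In acinar-like cells, pre-cancer against normal asks how cells with acinar markers differ between normal pancreas and 5 weeks after induction. The 2 sides did not cluster together: 242 of 243 and 308 of 308 such cells of normal samples 1 and 2 lay in a cluster with 0 pre-cancer cells, so a change within 1 cell type is not shown. By camera digestive enzymes shifted down, and MYC targets (35 up, 2 down) and cell cycle genes up, none of the 3 lists passing with an estimated correlation. Pnlip, pancreatic lipase (ENSMUSG00000046008, chromosome 19, 58652498 to 58681788), had 273758 ± 113142 CPM in normal cells (SD, n = 2) and 74.1 ± 34.0 in pre-cancer cells (n = 3), a log2 change of -11.85 ± 0.78 (SE, adjusted p = 4.12e-05). Nop58 (ENSMUSG00000026020, chromosome 1, 59684971 to 59719044), a factor in ribosome assembly, rose from 20.2 ± 2.92 to 302 ± 21 CPM, by 3.88 ± 0.23 (adjusted p = 1.87e-05). Of 12170 genes tested 2428 rose and 2453 fell at an adjusted p under 0.05 in edgeR, and 5893 had an unadjusted p under 0.05.

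Digestive enzymes had 27 down and 1 not passing (1 up and 27 down adjusted over the list alone, median -6.17, camera adjusted p = 7.7e-17, adjusted p = 0.122 with an estimated correlation). Gp2 was at -9.85 ± 0.41, adjusted p = 4.04e-06, and Prss2 at -8.70 ± 0.65, adjusted p = 5.84e-05. Their acinar marker subset had 10 down (10 down adjusted over the list alone, camera adjusted p = 5.83e-09, adjusted p = 0.0568 with an estimated correlation). Cela3b was at -7.10 ± 0.37. Acinar transcription factors had 8 down and 2 not passing (9 down adjusted over the list alone, median -2.27, camera adjusted p = 0.000223, adjusted p = 0.2 with an estimated correlation), but with total UMIs as the scale 3 rose and 2 fell. Gata6 was 726-fold lower (191 to 6151) in pooled CPM with its counting interval, Xbp1 fell from 772 ± 3.38 to 85.7 ± 10.2 CPM (-3.17 ± 0.18, adjusted p = 1.65e-05), and Creb3l1 was at -2.70 ± 0.25. Genes of the unfolded protein response had 14 down and 4 not passing (15 down adjusted over the list alone, median -1.99, camera adjusted p = 2.77e-06, adjusted p = 0.283 with an estimated correlation), while with total UMIs as the scale 9 rose and 2 fell. Trib3 and Ddit3 were at -4.37 ± 0.77 and -4.03 ± 0.67.

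MYC targets had 35 up, 2 down and 1 not passing (35 up and 2 down adjusted over the list alone, median 2.50, camera adjusted p = 1.19e-12, adjusted p = 0.302 with an estimated correlation). Tcof1, needed for ribosomal RNA transcription, rose from 3.44 ± 1.07 to 85.1 ± 6.91 CPM (4.69 ± 0.38, adjusted p = 6.65e-05), and the mitochondrial chaperone Hspd1 from 85.8 ± 19.1 to 1066 ± 85.3 (3.65 ± 0.28, adjusted p = 5.33e-05). Cell cycle genes had 29 up (29 up adjusted over the list alone, median 4.15 with genes at their bound, camera adjusted p = 1.19e-12, adjusted p = 0.376 with an estimated correlation). Birc5 rose by 4.97 ± 0.45 (adjusted p = 0.000106), Bub1 was at least 9.7-fold higher, Hmmr 96.1-fold higher (17.2 to 3797) and Mcm3 59.8-fold higher (16.5 to 494). Glycolysis and hypoxia genes had 12 up, 2 down and 5 not passing (12 up and 3 down adjusted over the list alone, median 1.64 with genes at their bound, camera adjusted p = 0.00832, adjusted p = 0.479 with an estimated correlation). Eno1 was at 3.66 ± 0.35, Ldha at 3.54 ± 0.41 and Pfkl at 2.87 ± 0.48. With total UMIs as the scale 37 MYC targets, 29 cell cycle genes and 16 glycolysis genes rose, and 25 digestive enzymes fell.

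Msi2 and Myc did not follow the MYC targets under this scale. Myc (ENSMUSG00000022346, chromosome 15, 61985391 to 61990374) had 30.9 ± 5.79 CPM in normal and 12.5 ± 3.72 in pre-cancer cells, a change of -1.29 ± 0.32 (adjusted p = 0.0124), but 1.26 with total UMIs as the scale. Msi2 (ENSMUSG00000069769, chromosome 11, 88339382 to 88718513) had 54.7 ± 15.5 and 24.5 ± 9.24 CPM, a change of -1.14 ± 0.36 (adjusted p = 0.0331), but 1.42 with total UMIs as the scale. Without normal sample 1 or 2 neither call held (adjusted p = 0.107 and 0.0569 for Myc, 0.253 and 0.0764 for Msi2), nor did that of Msi2 without pre-cancer sample 3 (0.0616). Neither passed with ambient RNA subtracted, after thinning or with total UMIs without enzyme genes as the scale. Digestive enzymes held 72.6% and 71.2% of UMIs in normal acinar-like cells and between 5.68% and 6.87% in pre-cancer cells. Total UMIs as the scale moved the median of all genes by 2.54 on the log2 scale, with 9186 genes up and 389 down, and total UMIs without enzyme genes by 0.82, with 4918 up and 1243 down. Without any scaling, enzyme UMIs per acinar-like cell were 8895 and 9947 in normal samples against 137, 192 and 133 in pre-cancer samples. MYC target UMIs per cell were 8.54 and 11.7 against 49.9, 78.4 and 45.1, and cell cycle UMIs 0.222 and 0.669 against 7.26, 10.6 and 5.99. Median mitochondrial UMIs were 0.55% and 0.56% in normal and between 6.37% and 7.46% in pre-cancer acinar-like cells.

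**Figure D2:**
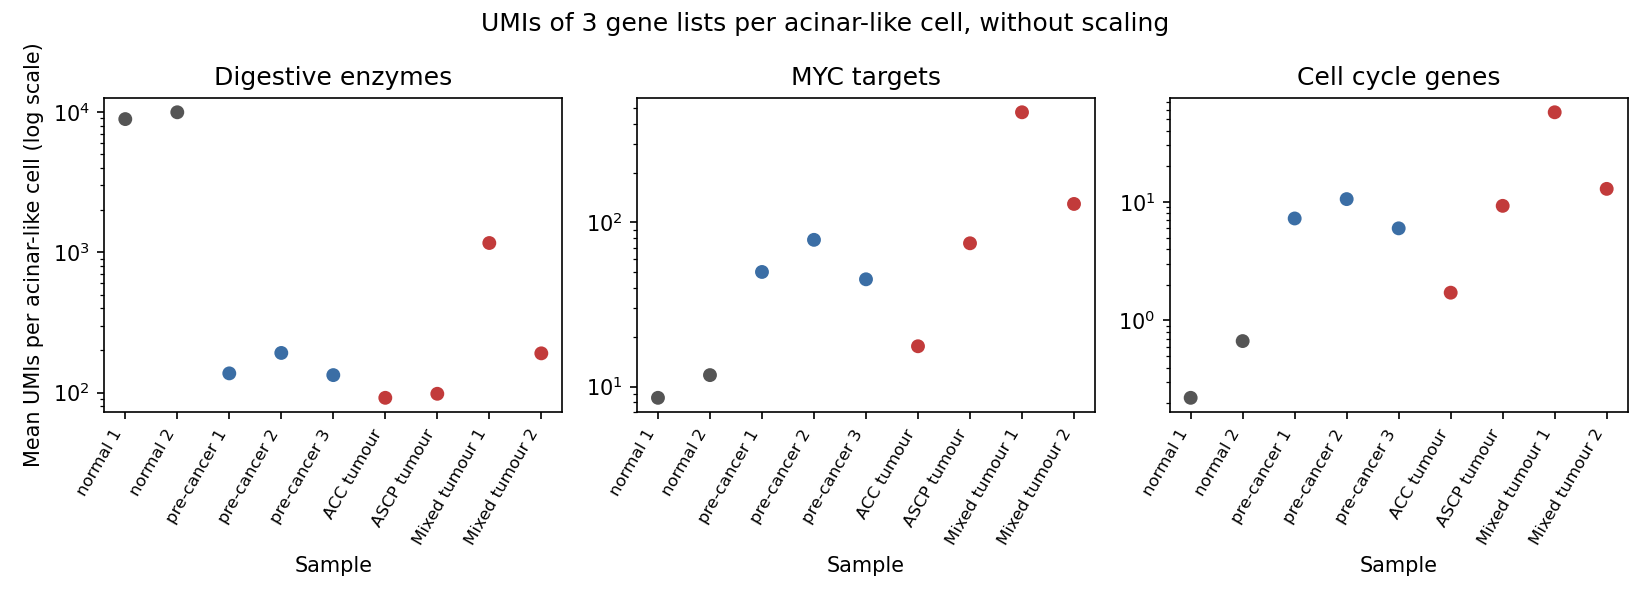
Mean UMIs per acinar-like cell without any scaling (log axis) for digestive enzymes, MYC targets and cell cycle genes, 1 point per sample grouped by stage. MYC target UMIs lie at 11.7 or below in both normal samples and at 45.1 or above in the 3 pre-cancer samples, the opposite order to digestive enzymes.

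Genes of amino acid supply, regeneration and duct identity were mixed in direction. Serine and amino acid supply had 4 up, 6 down and 6 not passing (5 up and 6 down adjusted over the list alone, camera adjusted p = 0.191), while under total UMIs 12 rose and 3 fell. Slc7a11 was at -7.85 ± 0.53, Chac1 at -6.39 ± 0.31 and Pycr1 at -4.30 ± 0.39. Reg and acute phase genes had 1 up, 5 down and 5 not passing (1 up and 5 down adjusted over the list alone, camera adjusted p = 0.0612). Reg2 was at -7.58 ± 0.89, Reg3d at -5.57 ± 0.25 and Pigr at -4.67 ± 0.67. Duct and metaplasia genes had 5 up, 8 down and 7 not passing (5 up and 9 down adjusted over the list alone, median -0.93 with genes at their bound, camera adjusted p = 0.222), and under total UMIs 10 rose and 3 fell. Tm4sf4 was at -5.52 ± 1.08, Spp1 at -5.20 ± 1.48 and Anxa3 83.7-fold lower (6.7 to 4396). Gastric metaplasia genes had 2 down and 7 not passing (2 down adjusted over the list alone, camera adjusted p = 0.745). Tff2 was at -6.79 ± 0.34, adjusted p = 9.53e-06, and Agr2 102-fold lower (27 to 571). The fitted median of that list was 1.88 although its test direction was down, and -3.46 with genes at their bound. Squamous and basal genes had 7 not passing (none adjusted over the list alone, camera adjusted p = 0.819). Perp was at 0.23 ± 0.30 (adjusted p = 0.587) and Sfn at 0.67 ± 0.51 (adjusted p = 0.334).

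Ribosomal proteins had 7 up, 9 down and 61 not passing (1 up and 1 down adjusted over the list alone, median -0.05, camera adjusted p = 0.596). Rpl41 was at -0.97 ± 0.23, but at 1.59 with total UMIs as the scale, under which 76 members rose. There were 54 that rose with total UMIs without enzymes. Of the members that rose, Rpl7l1 (1.19 ± 0.34) is a gene similar to Rpl7, and Rps19bp1 (1.15 ± 0.24) encodes a protein that binds RPS19. The p53 and apoptosis list had 4 up, 4 down and 4 not passing (4 up and 4 down adjusted over the list alone, camera adjusted p = 0.873), and under total UMIs 10 rose and 0 fell. Pmaip1 was at least 4.6-fold higher, Eda2r 6.9-fold higher (1.9 to 57.0) and Trp53inp1 at -1.95 ± 0.35, but at 0.61 under total UMIs. Interferon response genes had 2 up and 7 not passing (2 up adjusted over the list alone, camera adjusted p = 0.126). Bst2 was at 1.77 ± 0.32 and Ifitm3 at 1.59 ± 0.43. Antigen presentation had 4 down and 7 not passing (4 down adjusted over the list alone, camera adjusted p = 0.215), but under total UMIs 6 rose and 0 fell. Cd74, the class 2 chaperone, was at -4.72 ± 1.09, Tapbp at -1.27 ± 0.31 and H2-K1 at -1.06 ± 0.25, these 2 being at 1.29 and 1.49 under total UMIs. Dissociation and heat shock genes, which tissue handling can raise, had 5 up, 1 down and 12 not passing (5 up and 1 down adjusted over the list alone, camera adjusted p = 0.0776). Hsp90aa1 was at 3.28 ± 0.28, adjusted p = 9.43e-05, Ier3 at 2.44 ± 0.39 and Atf3 at 1.96 ± 0.50. Ier3 was at -0.71 with cells named by their own marker score and -0.27 with the low-UMI enzyme cluster included. Progenitor and Musashi genes had 1 up, 3 down and 7 not passing (1 up and 3 down adjusted over the list alone, camera adjusted p = 0.215), and under total UMIs 6 rose and 1 fell. Aldh1a1 was at 0.97 ± 0.32 and Dclk1 at least 260.5-fold lower, its 28 counts all in normal sample 2.

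Of the markers of other cells, the endocrine and stromal lists shifted down by camera but did not pass with an estimated correlation. Endocrine markers had 7 down (7 down adjusted over the list alone, median -10.41, camera adjusted p = 3.18e-07, adjusted p = 0.0568 with an estimated correlation). The hormone gene Ppy was at -11.71 ± 0.62, Ins2 at -10.55 ± 0.61 and Sst 2540.1-fold lower (445 to 101415). Stromal markers had 6 down (6 down adjusted over the list alone, median -6.48 with genes at their bound, camera adjusted p = 0.00367, adjusted p = 0.41 with an estimated correlation), Dcn being at least 223-fold lower and Col1a1 and Col1a2 at least 46.5-fold lower. Mesenchymal transition genes had 2 down and 9 not passing (2 down adjusted over the list alone, camera adjusted p = 0.287). Itga5 was at -4.42 ± 0.99 and Sparc 195-fold lower (25.1 to 8806). Immune markers had 1 down and 5 not passing (1 down adjusted over the list alone, camera adjusted p = 0.93), the 1 being Cd74, with a fitted median of 1.57 against a test direction of down and -3.82 with genes at their bound. Erythroid markers had too few tested members for a list test, with Hbb-bs at -2.28 (adjusted p = 0.452, 0.28 under total UMIs) and Hbb-bt at -5.11 (adjusted p = 0.0616).

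Outside the lists, the largest rises were Smpdl3b at least 61.7-fold higher, Tmem266 145-fold higher (26 to 5719.6), S100g at 6.74 ± 0.91, adjusted p = 0.000934, the histone gene Hist1h2ap at 5.57 ± 0.72 and Smc2 at 5.43 ± 0.43. The largest falls were Tmed11, 16217-fold lower (2899 to 641637), the insulin gene Ins1, itself 1 of the endocrine markers, at -10.30 ± 0.42, and Xist, the RNA of the inactive X chromosome, from 452 ± 135 to 0.131 ± 0.0520 CPM (-11.56 ± 2.67, adjusted p = 0.0166). Without normal sample 2 the count of genes was 3197, and 46 of 62 called named genes were still called. With ambient RNA subtracted it was 1148, and 29 of 59 were.

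**Figure D3:**
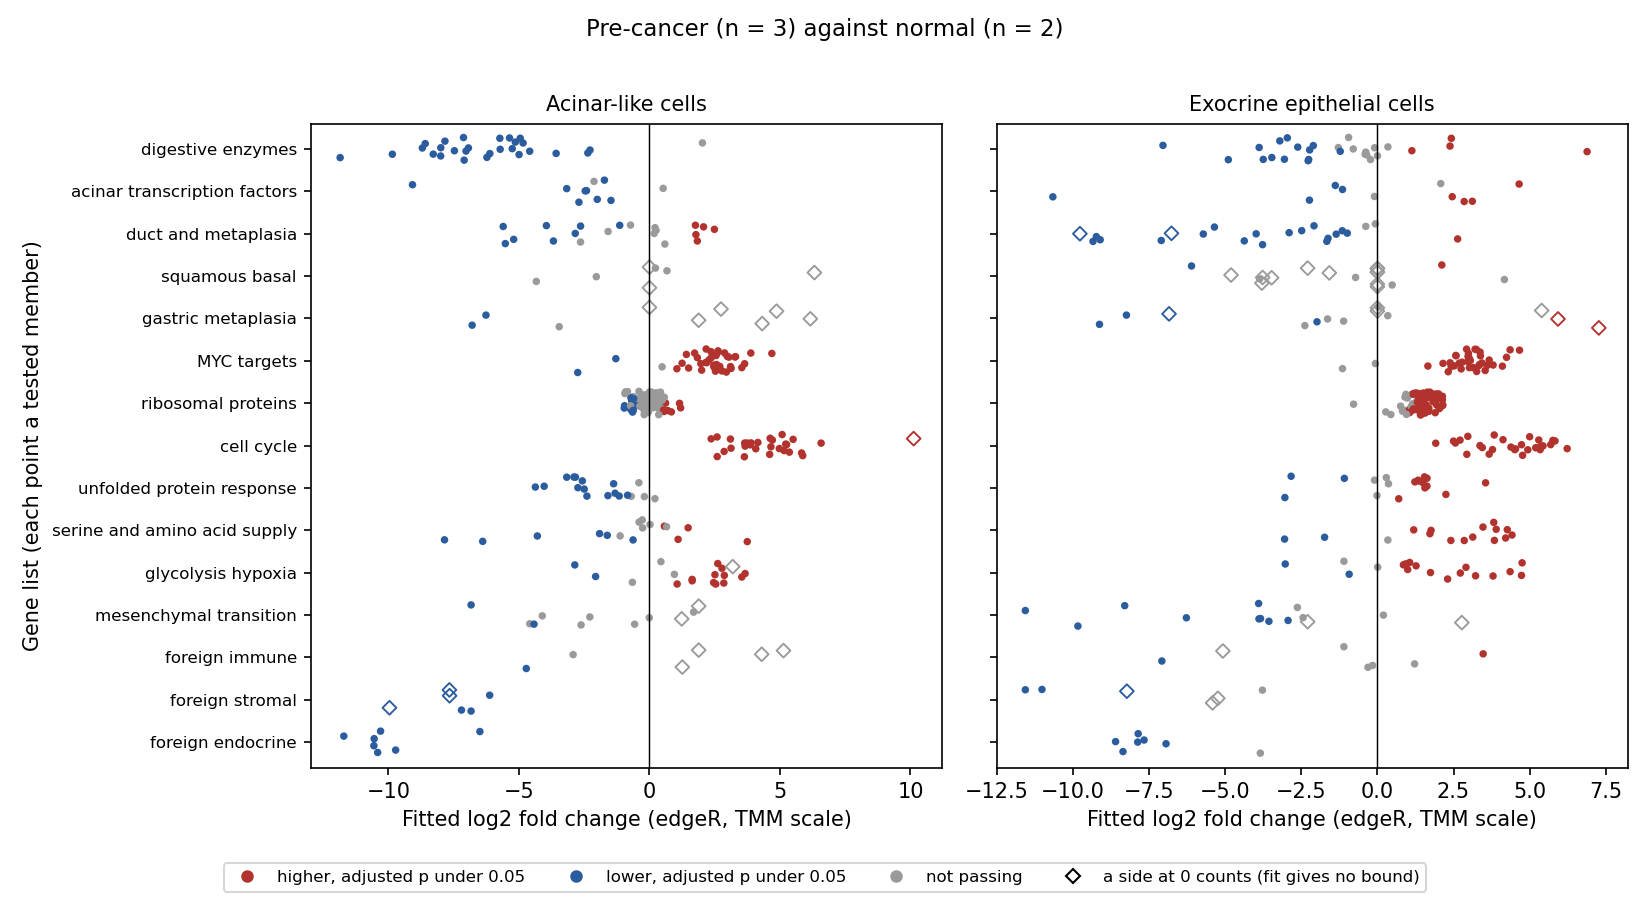
Log2 fold change of each list member (points), pre-cancer against normal, in acinar-like and exocrine epithelial cells. Genes that have a side at 0 counts are marked as having no bound, and list medians are not drawn. In acinar-like cells the median is -6.17 for digestive enzymes and 2.50 for MYC targets, both of the same sign with total UMIs as the scale, whereas acinar transcription factors and the unfolded protein response change sign under it.

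Over all exocrine epithelial cells, the same step asks how the exocrine compartment changed as a whole. By camera cell cycle genes and MYC targets shifted up and duct genes down, and with an estimated correlation only cell cycle genes passed of these 3. Here the normal side is mostly ductal-like and the pre-cancer side acinar-like, so differences between these cell types are part of every change. The cyclin gene Ccna2 (ENSMUSG00000027715, chromosome 3, 36564865 to 36572150) had 2.82 ± 0.0770 CPM in normal (SD, n = 2) and 153 ± 16 in pre-cancer samples (n = 3), a rise of 5.76 ± 0.23 (adjusted p = 5.19e-06). The duct gene Tm4sf4 fell from 954 ± 77.2 to 1.55 ± 1.43 CPM (-9.23 ± 0.63, adjusted p = 2.03e-05). Of 15148 genes tested 3942 rose and 5008 fell at an adjusted p under 0.05 in edgeR, and 9647 had an unadjusted p under 0.05. Msi2 fell from 125 ± 41.9 to 38.2 ± 14.4 CPM (-1.71 ± 0.34, adjusted p = 0.00315). Myc was at -0.07 ± 0.43 (adjusted p = 0.918), with 0.81 without normal sample 1 and 0.10 without pre-cancer sample 2.

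MYC targets had 36 up and 2 not passing (36 up adjusted over the list alone, median 3.02, camera adjusted p = 4.17e-16, adjusted p = 0.252 with an estimated correlation). Srm was at 4.67 ± 0.35 and Cad at 4.24 ± 0.20, adjusted p = 6.28e-06. Cell cycle genes had 29 up (29 up adjusted over the list alone, median 4.54, camera adjusted p = 5.2e-16), a call that held with an estimated correlation (adjusted p = 0.0219). Ccnb1 rose by 6.23 ± 0.37 and Birc5 by 5.83 ± 0.29. Ribosomal proteins had 63 up and 14 not passing (68 up adjusted over the list alone, median 1.49, camera adjusted p = 2.26e-13, adjusted p = 0.614 with an estimated correlation). Rps6 was at 2.15 ± 0.29, Rpl13a at 2.14 ± 0.58 and Rpl12 at 2.13 ± 0.32. Serine and amino acid supply had 13 up, 2 down and 1 not passing (13 up and 2 down adjusted over the list alone, median 2.99, camera adjusted p = 1.97e-05, adjusted p = 0.0873 with an estimated correlation). Psat1 rose by 4.42 ± 0.24, Slc1a5 by 4.27 ± 0.36 and Shmt2 by 4.21 ± 0.24. Glycolysis and hypoxia genes had 14 up, 2 down and 3 not passing (15 up and 2 down adjusted over the list alone, median 1.27, camera adjusted p = 0.000461, adjusted p = 0.252 with an estimated correlation). Car9 was at 4.75 ± 0.32, Hk2 at 4.73 ± 0.40 and Ldha at 4.36 ± 0.39. The unfolded protein response had 11 up, 3 down and 4 not passing (11 up and 3 down adjusted over the list alone, median 1.28, camera adjusted p = 0.0191, adjusted p = 0.252 with an estimated correlation). Sdf2l1 was at 3.55 ± 0.25, Trib3 at -3.04 ± 0.54 and Ddit3 at -2.83 ± 0.40.

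Duct and metaplasia genes had 1 up, 19 down and 2 not passing (1 up and 19 down adjusted over the list alone, median -3.29 with genes at their bound, camera adjusted p = 0.000125, adjusted p = 0.32 with an estimated correlation), with Mmp7 at least 114-fold lower and Anxa3 836-fold lower (231 to 6908). Mesenchymal transition genes had 9 down and 5 not passing (10 down adjusted over the list alone, median -3.70 with genes at their bound, camera adjusted p = 0.0079, adjusted p = 0.585 with an estimated correlation). Vim was at -8.30 ± 1.22 and Sparc 4359.8-fold lower (782 to 172232). Antigen presentation had 10 down and 3 not passing (10 down adjusted over the list alone, median -1.89 with genes at their bound, camera adjusted p = 0.0393, adjusted p = 0.707 with an estimated correlation). Cd74 was at -7.08 ± 1.40, Ciita at least 9.0-fold lower and H2-Aa 156-fold lower (42.8 to 1288). Digestive enzymes had 4 up, 14 down and 10 not passing (4 up and 14 down adjusted over the list alone, camera adjusted p = 0.124). Pnlip was at -7.04 ± 0.90, Gp2 at -4.90 ± 0.58 and Prss1 at 6.89 ± 1.2 but at -8.03 with ambient RNA subtracted. Their acinar marker subset had 5 down and 5 not passing (5 down adjusted over the list alone, camera adjusted p = 0.0791). Prss2 was at -3.88 ± 0.52 and Cela3b at -2.26 ± 0.32. Acinar transcription factors had 4 up, 4 down and 2 not passing (4 up and 4 down adjusted over the list alone, camera adjusted p = 0.666). Gata4 was at 4.66 ± 0.28, Rbpjl at 3.12 ± 0.42 and Gata6 1772-fold lower (606 to 8597).

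Of the remaining lists only endocrine markers passed camera, with 6 down and 1 not passing (7 down adjusted over the list alone, median -7.86, camera adjusted p = 0.00176, adjusted p = 0.18 with an estimated correlation). Ppy was at -8.60 ± 0.64, Ins2 at -7.87 ± 0.65 and Sst 364-fold lower (65.1 to 14420.4). Stromal markers had 3 down and 3 not passing (3 down adjusted over the list alone, camera adjusted p = 0.105). Igfbp7 was at -11.02 ± 0.48 and Dcn at least 22.1-fold lower. Immune markers had 1 up, 1 down and 5 not passing (1 up and 1 down adjusted over the list alone, camera adjusted p = 0.968), Coro1a being 12.2-fold higher (3.7 to 62.7), with a median of -0.31 against a test direction of up. Erythroid markers had 4 not passing (none adjusted over the list alone, camera adjusted p = 0.911). Hbb-bs was at 0.34 (adjusted p = 0.913, -0.27 with total UMIs without enzymes as the scale) and Hba-a2 5.3-fold lower (1.2 to 48.2). Squamous and basal genes had 1 up, 1 down and 16 not passing (1 up and 1 down adjusted over the list alone, camera adjusted p = 0.968). Perp was at 2.12 ± 0.19 and Krt17 at -6.10 ± 0.44, with a median of -0.36 against a test direction of up. Gastric metaplasia genes had 2 up, 4 down and 8 not passing (2 up and 4 down adjusted over the list alone, camera adjusted p = 0.911). Cldn18 was at least 24.3-fold higher, Aqp5 789.7-fold lower (218 to 6525) and Cldn2 339-fold lower (93.5 to 2801). Progenitor and Musashi genes had 1 up, 7 down and 3 not passing (1 up and 7 down adjusted over the list alone, camera adjusted p = 0.165), Hes1 at -2.74 ± 0.49, Msi1 at -3.54 ± 1.05 and Dclk1 at least 119-fold lower. Reg and acute phase genes had 3 up, 4 down and 5 not passing (3 up and 4 down adjusted over the list alone, camera adjusted p = 0.911). Lcn2 was at -7.60 ± 0.82, Pigr at -6.00 ± 0.61 and Reg3g at 4.38 ± 1.02. Interferon response had 3 up, 4 down and 7 not passing (3 up and 4 down adjusted over the list alone, camera adjusted p = 0.666). Ifit3 was at -4.54 ± 0.90, Ifit2 at -4.44 ± 0.88 and Ifit1 at -3.51 ± 0.42. The p53 and apoptosis list had 6 up, 3 down and 5 not passing (6 up and 3 down adjusted over the list alone, camera adjusted p = 0.165). Pmaip1 was at 6.65 ± 0.47, Eda2r at 3.40 ± 0.59 and Fas at -3.69 ± 0.43. Dissociation and heat shock genes had 3 up, 5 down and 10 not passing (2 up and 4 down adjusted over the list alone, camera adjusted p = 0.666). Hsp90aa1 was at 2.60 ± 0.30, Hspa1b at 1.89 ± 0.65 and Dusp1 at -4.15 ± 0.54.

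Outside the lists, Smpdl3b was at least 2418-fold higher, Gc was at 7.40 ± 0.65, Tmem266 at 7.37 ± 0.34, Tdh at 6.99 ± 0.49 and S100g at 7.27 ± 1.05. Slc28a3 was 8785-fold lower (1576 to 346999.9), Ankrd1 5304-fold lower (952 to 209524) and Rbms3 4028-fold lower (1115 to 33264). Dcdc2a was at -11.82 ± 0.78, Fmo2 at -11.76 ± 0.57 and Xist at -12.05 ± 2.65, adjusted p = 0.00697. Summed over Y-linked genes, normal samples held 0.03 CPM or less and pre-cancer samples 60.4 or more. Total UMIs as the scale moved the median of all genes by -0.30 and total UMIs without enzymes by -0.50, the latter with 2728 genes up and 6618 down, and no list that passed changed sign under either. With ambient RNA subtracted 3258 genes passed, and 46 of 71 called named genes were still called.

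From pre-cancer to tumours, acinar-like cells of the 4 tumours were compared with those of the 3 pre-cancer samples. The sides mostly lay in different clusters: 1 held 1609 of 1653 ACC cells, another 45 of 73 ASCP and 363 of 457 Mixed tumour 2 cells, and 2 more 211 and 175 of 509 Mixed tumour 1 cells, with at most 37 pre-cancer cells in any, so a change within 1 cell type is not shown. Myc rose, 3 digestive enzymes fell, and stromal markers had 4 of 5 members up, in a list that did not pass with an estimated correlation. Myc went from 12.2 ± 3.62 CPM (SD, n = 3) to 49.3 ± 24.1 (n = 4), a change of 2.09 ± 0.37 (adjusted p = 0.0246), with each tumour above each pre-cancer sample. Chymotrypsin C, Ctrc (ENSMUSG00000062478, chromosome 4, 141814962 to 141846359), fell from 81.3 ± 34.4 to 5.57 ± 1.17 CPM (-3.99 ± 0.34, adjusted p = 0.000885). Lcn2 (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252), an iron-scavenging protein of inflammation, rose from 0.379 ± 0.242 to 299 ± 365 CPM (9.52 ± 1.66, adjusted p = 0.0312). Msi2 was at 0.30 ± 0.34 (adjusted p = 0.718). Of 11152 genes tested 378 rose and 98 fell at an adjusted p under 0.05 in edgeR, and 2182 had an unadjusted p under 0.05.

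Digestive enzymes had 3 down and 25 not passing (1 up and 5 down adjusted over the list alone, median -0.14, camera adjusted p = 0.00127, adjusted p = 0.672 with an estimated correlation). The 3 were Ctrc and the trypsinogen paralogs Try10 (-3.18 ± 0.37) and Try4 (-2.12 ± 0.42), Try4 being at 1.39 with ambient RNA subtracted. Their acinar marker subset had 1 down and 9 not passing (1 down adjusted over the list alone, camera adjusted p = 0.272). Cell cycle genes had 2 down and 27 not passing (3 down adjusted over the list alone, median -0.48, camera adjusted p = 0.00136, adjusted p = 0.672 with an estimated correlation). Mcm6 was at -0.98 ± 0.21 and Ccnb2 at -0.91 ± 0.22. MYC targets had 1 up and 37 not passing, the 1 being Myc itself (1 up adjusted over the list alone, camera adjusted p = 0.316). Reg and acute phase genes had 4 up and 7 not passing (4 up adjusted over the list alone, camera adjusted p = 0.028, adjusted p = 0.497 with an estimated correlation), with Lcn2, Reg2 at 3.30 ± 0.73, Saa3 at 4.37 ± 1.005 and Hp 154-fold higher (26.7 to 6145). Duct and metaplasia genes had 3 up and 17 not passing (3 up adjusted over the list alone, camera adjusted p = 0.352). S100a6 was at 8.64 ± 1.10, adjusted p = 0.0158, Onecut2 at 6.08 ± 0.87 and Anxa3 246-fold higher (43.3 to 9785). Gastric metaplasia genes had 1 up and 5 not passing (3 up adjusted over the list alone, median 2.86 with genes at their bound, camera adjusted p = 0.00182, adjusted p = 0.283 with an estimated correlation), Cldn2 being 53.2-fold higher (14 to 451).

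Stromal and immune markers shifted up by camera but did not pass with an estimated correlation. Stromal markers had 4 up and 1 not passing (5 up adjusted over the list alone, median 6.45 with genes at their bound, camera adjusted p = 0.00127, adjusted p = 0.497 with an estimated correlation), Col1a2 being at least 113-fold higher and Col3a1 161-fold higher (54.4 to 787), and Sparc 354-fold higher (62.7 to 14071). Immune markers had 3 up and 1 not passing (4 up adjusted over the list alone, median 5.46 with genes at their bound, camera adjusted p = 0.028, adjusted p = 0.646 with an estimated correlation), Lyz2 448-fold higher (153 to 2180.0), Tyrobp 223-fold higher (39.2 to 8895) and Cd74 at 4.51 ± 1.07. Cd74 was also the 1 member of antigen presentation that rose, that list having 1 up and 7 not passing (1 up adjusted over the list alone, camera adjusted p = 0.696). Mesenchymal transition genes had 3 up and 4 not passing (5 up adjusted over the list alone, median 3.08 with genes at their bound, camera adjusted p = 0.00182, adjusted p = 0.283 with an estimated correlation). Cdh2 was at 5.22 ± 1.29 and Vim at 5.15 ± 1.24. Lyz2 had 22.9 CPM in the ACC tumour, 30.9 in Mixed tumour 1 and 0 in the ASCP tumour and Mixed tumour 2.

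Serine and amino acid supply had 2 up and 14 not passing (2 up and 1 down adjusted over the list alone, camera adjusted p = 0.974). Slc7a11 was at 4.57 ± 0.74 and Chac1 at 2.38 ± 0.44. The unfolded protein response had 1 up, 1 down and 16 not passing (2 up and 2 down adjusted over the list alone, camera adjusted p = 0.864). Ddit3 was at 2.59 ± 0.52, Edem1 was at -1.02 ± 0.20 and the list median was 0.01 against a test direction of down. Glycolysis and hypoxia genes had 1 up and 18 not passing (4 up adjusted over the list alone, median 0.55, camera adjusted p = 0.00182, adjusted p = 0.646 with an estimated correlation), the 1 being the peptide gene Adm (4.27 ± 1.04). Progenitor and Musashi genes had 1 up and 9 not passing (2 up and 1 down adjusted over the list alone, camera adjusted p = 0.805). Aldh1b1 was at 2.90 ± 0.52 and the list median was -0.02 against a test direction of up. Interferon response had 9 not passing (4 down adjusted over the list alone, median -1.31, camera adjusted p = 0.00127, adjusted p = 0.497 with an estimated correlation). Ifitm3 was at -1.09 and Bst2 at -0.65. Ribosomal proteins had 77 not passing (none adjusted over the list alone, camera adjusted p = 0.00533, adjusted p = 0.777 with an estimated correlation). Rpl13 was at 0.17. Acinar transcription factors had 10 not passing (1 up adjusted over the list alone, camera adjusted p = 0.272). Xbp1 was at 0.28 and Rbpjl at -0.31. Squamous and basal genes had 5 not passing (2 up and 1 down adjusted over the list alone, camera adjusted p = 0.272). Perp was at -0.73 (adjusted p = 0.138) and Sfn at 0.55. The p53 and apoptosis list had 12 not passing (3 up adjusted over the list alone, camera adjusted p = 0.175). The cell cycle inhibitor Cdkn1a was at 1.88 (adjusted p = 0.109) and Bax at 0.16. Dissociation and heat shock genes had 18 not passing (none adjusted over the list alone, camera adjusted p = 0.862). Hsp90aa1 was at -0.17 and Jun at 0.18. Endocrine markers had 7 not passing (none adjusted over the list alone, camera adjusted p = 0.316). Ins2 was at -1.62 and Ins1 10.3-fold lower (1.6 to 424). The erythroid gene Hbb-bs was 41.0-fold lower (7.2 to 1639), with adjusted p = 0.335.

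Outside the lists, the small heat shock protein gene Hspb1 rose by 4.23 ± 0.90, Sh3bgrl3 by 1.93 ± 0.34, Tmem160 by 1.32 ± 0.29 and Ndufa1 by 1.21 ± 0.25. Tdh (-3.13 ± 0.48), Ifi27 (-2.48 ± 0.44) and the acinar water channel Aqp12 (-1.88 ± 0.33) fell. The count of genes moved with single libraries: 3, 15 and 5 genes without pre-cancer sample 1, 2 or 3, 791 without the ACC tumour, 227 without the ASCP tumour, and 26 and 1661 without Mixed tumour 1 or 2. Of 35 called named genes 1, 3 and 2 were still called without pre-cancer sample 1, 2 or 3. With ambient RNA subtracted edgeR called 0 genes, with 1127 at an unadjusted p under 0.05.

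Over all exocrine epithelial cells, the lists of duct, squamous and gastric epithelium shifted up by camera in the tumours, and those of cell cycle genes and MYC targets down. Most members did not pass, save 9 of 12 gastric genes, and none of these 5 lists passed with an estimated correlation (adjusted p = 0.301 to 0.713). S100a6 (ENSMUSG00000001025, chromosome 3, 90612882 to 90624181), a calcium-binding protein of duct and metaplastic cells, rose from 0.295 ± 0.0630 CPM (SD, n = 3) to 3054 ± 2473 (n = 4), by 13.27 ± 2.16 (adjusted p = 0.0146), and had 9.58 CPM in the ACC tumour. Tff1 (ENSMUSG00000024032, chromosome 17, 31161395 to 31165277), a gastric mucosal peptide, rose by 11.52 ± 2.66 (adjusted p = 0.0355), with 0 CPM in the ACC tumour. Ccna2 fell from 152 ± 16 to 58.3 ± 6.5 CPM (-1.38 ± 0.16, adjusted p = 0.00637), with each tumour below each pre-cancer sample. Myc rose from 19.3 ± 5.68 to 57.4 ± 11.6 CPM (1.58 ± 0.39, adjusted p = 0.0366), and Msi2 was at 0.65 ± 0.33 (adjusted p = 0.213). Of 14012 genes tested 1189 rose and 502 fell at an adjusted p under 0.05 in edgeR, and 4642 had an unadjusted p under 0.05.

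Squamous and basal genes had 7 up and 10 not passing (15 up adjusted over the list alone, median 5.76 with genes at their bound, camera adjusted p = 9.63e-05, adjusted p = 0.662 with an estimated correlation). The cornified envelope genes Sprr1a and Ivl were 9264-fold higher (1662 to 365962) and at least 126-fold higher, and the serpin gene Serpinb5 at least 309-fold higher. Gastric metaplasia genes had 9 up and 3 not passing (12 up adjusted over the list alone, median 8.47 with genes at their bound, camera adjusted p = 6.87e-05, adjusted p = 0.632 with an estimated correlation). Ctse was at 9.19 ± 1.93 and Gkn3 675-fold higher (230.5 to 3274). Duct and metaplasia genes had 6 up and 16 not passing (9 up adjusted over the list alone, median 1.67 with genes at their bound, camera adjusted p = 0.00782, adjusted p = 0.713 with an estimated correlation), Mmp7 being at least 908-fold higher. Mesenchymal transition genes had 8 up and 5 not passing (13 up adjusted over the list alone, median 5.32 with genes at their bound, camera adjusted p = 2e-05, adjusted p = 0.353 with an estimated correlation), with the transcription factor Snai1 114-fold higher (20 to 4545). Stromal markers, a sign of other cells, had 3 up and 3 not passing (6 up adjusted over the list alone, median 6.60 with genes at their bound, camera adjusted p = 0.000578, adjusted p = 0.353 with an estimated correlation). Igfbp7 was at 6.57 ± 0.79, Sparc 422-fold higher (75.4 to 16724) and Col1a2 at least 98.8-fold higher. Immune markers had 1 up and 6 not passing (5 up adjusted over the list alone, median 4.40 with genes at their bound, camera adjusted p = 0.0283, adjusted p = 0.662 with an estimated correlation), the 1 being Lyz2, 455-fold higher (155 to 2211).

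Cell cycle genes had 10 down and 19 not passing (20 down adjusted over the list alone, median -0.83, camera adjusted p = 4.28e-10, adjusted p = 0.301 with an estimated correlation). Mcm2 was at -1.33 ± 0.31 and Mcm5 at -1.24 ± 0.27. MYC targets had 1 up, 7 down and 30 not passing, the 1 being Myc (1 up and 13 down adjusted over the list alone, median -0.50, camera adjusted p = 8.65e-08, adjusted p = 0.353 with an estimated correlation). Odc1 was at -1.12 ± 0.24 and Cad at -0.92 ± 0.17. Digestive enzymes had 3 down and 25 not passing (3 down adjusted over the list alone, median -0.86, camera adjusted p = 2.9e-06, adjusted p = 0.662 with an estimated correlation). Ctrc was at -5.01 ± 0.49, Try10 at -3.97 ± 0.79 and Try4 at -3.07 ± 0.68, Try4 being at 0.34 with ambient RNA subtracted. Their acinar marker subset had 1 down and 9 not passing (1 down adjusted over the list alone, camera adjusted p = 0.00782, adjusted p = 0.662 with an estimated correlation). Acinar transcription factors had 1 up, 2 down and 7 not passing (1 up and 2 down adjusted over the list alone, camera adjusted p = 0.0514). Bhlha15 was at -2.03 ± 0.52, Nr5a2 at -1.64 ± 0.45 and Gata6 15.2-fold higher (4.9 to 76.7). Serine and amino acid supply had 1 up, 4 down and 11 not passing (2 up and 7 down adjusted over the list alone, median -0.55, camera adjusted p = 0.00782, adjusted p = 0.353 with an estimated correlation). Asns was at -1.25 ± 0.31, Shmt1 at -1.03 ± 0.25 and Slc7a11 at 5.60 ± 1.11.

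The unfolded protein response had 2 up, 3 down and 13 not passing (3 up and 5 down adjusted over the list alone, camera adjusted p = 0.0514). Ddit3 was at 2.36 ± 0.44, Trib3 at 2.32 ± 0.56 and Edem1 at -1.61 ± 0.29. Glycolysis and hypoxia genes had 4 up, 1 down and 14 not passing (4 up and 1 down adjusted over the list alone, camera adjusted p = 0.155). Adm was at 6.07 ± 0.96 and Egln3 at 3.76 ± 1.04, and Hk1 at 1.62 ± 0.39. The p53 and apoptosis list had 3 up and 11 not passing (5 up adjusted over the list alone, camera adjusted p = 0.179). Cdkn2a was at 4.55 ± 0.98, Phlda3 at 3.46 ± 0.94 and Fas at 3.19 ± 0.71. Reg and acute phase genes had 2 up and 9 not passing (5 up adjusted over the list alone, camera adjusted p = 0.506). Lcn2 was at 9.48 ± 1.72 and Hp 109.7-fold higher (19.2 to 4374). Interferon response had 1 down and 13 not passing (2 up and 2 down adjusted over the list alone, camera adjusted p = 0.283). Ifitm3 was at -2.02 ± 0.42 and the list median was 0.33 against a test direction of down. Endocrine markers had 1 down and 6 not passing (1 down adjusted over the list alone, camera adjusted p = 0.439), Ins1 being 19.3-fold lower (3.1 to 799.9). Ribosomal proteins had 77 not passing (none adjusted over the list alone, camera adjusted p = 0.233). Rpl13 was at 0.17. Progenitor and Musashi genes had 11 not passing (none adjusted over the list alone, camera adjusted p = 0.499). Cd24a was at -0.38 and Hes1 at -0.20. Antigen presentation had 12 not passing (none adjusted over the list alone, camera adjusted p = 0.179). H2-K1 was at 0.37 and H2-D1 at 1.03. Dissociation and heat shock genes had 18 not passing (none adjusted over the list alone, camera adjusted p = 0.663). Hsp90aa1 was at -0.58 and Jun at -0.01, with a median of 0.06 against a test direction of down. Erythroid markers had 3 not passing (none adjusted over the list alone, camera adjusted p = 0.873), Hbb-bs 77.4-fold lower (13.5 to 3092) and Hba-a2 9.2-fold higher (2.2 to 82.4), with a fitted median of 0.64 against a test direction of down.

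Outside the lists, Igfbp2, which binds insulin-like growth factors, was 2303-fold higher (637 to 19025), and AA467197 (10.503 ± 2.19) and the annexin Anxa1 (10.02 ± 1.91) rose. Onecut2, a member of the duct and metaplasia list, rose by 10.42 ± 1.44. Tdh (-4.36 ± 0.44), S100g (-3.15 ± 0.84) and the acinar disulfide isomerase Pdia2 (-2.18 ± 0.58) fell. The count of genes was 44, 46 and 33 without pre-cancer sample 1, 2 or 3, and 420 without Mixed tumour 1. It was 2669 without the ACC tumour, 2488 without Mixed tumour 2 and 1951 without the ASCP tumour. Of 50 called named genes 4, 2 and 3 were still called without pre-cancer sample 1, 2 or 3. With ambient RNA subtracted edgeR called 26 genes, with 2739 at an unadjusted p under 0.05.

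**Figure D4:**
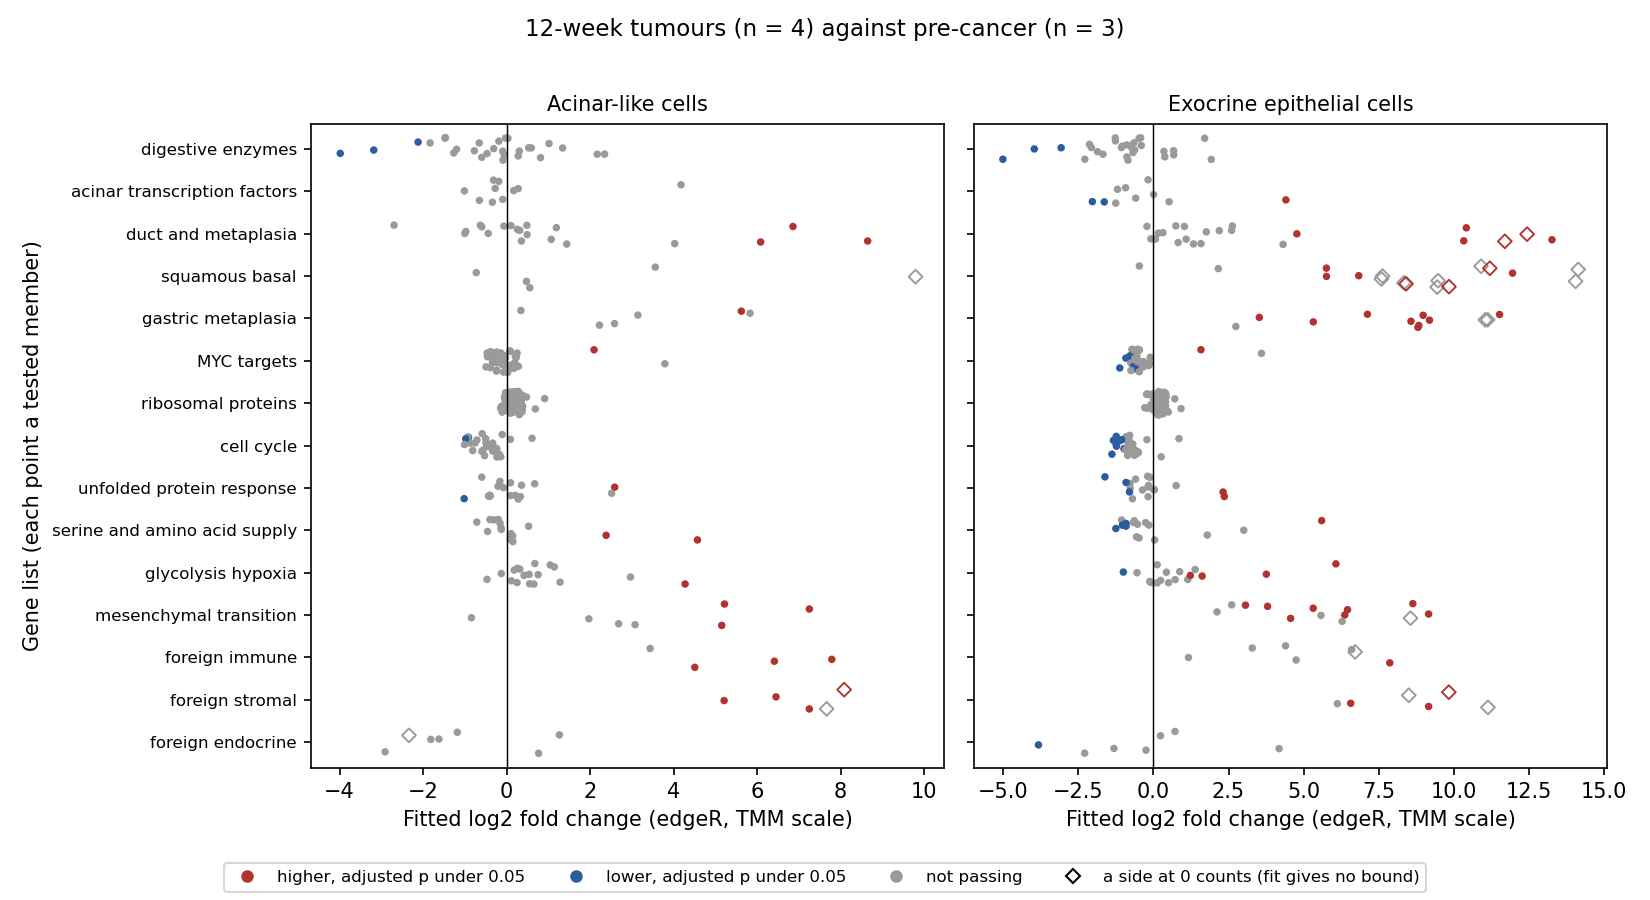
Log2 fold change of each list member (points), 12-week tumours against pre-cancer, in acinar-like and exocrine epithelial cells. Genes that have a side at 0 counts are marked as having no bound, and list medians are not drawn. In exocrine epithelial cells 16 of 17 squamous and 12 of 12 gastric list members lie to the right of 0, with medians of 5.76 and 8.48 at the bound, and the cell cycle median is -0.84.

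The tumour types were compared side by side without a test, since the ACC and ASCP types have 1 sample each. Exocrine epithelial cells of the ACC tumour, all of them named acinar-like, had more enzyme UMIs, and those of the ASCP tumour more squamous and duct ones. Enzymes held 7.05% of UMIs in these ACC cells and 6.03% in that tumour's empty droplets, against 0.506% and 0.451% for the ASCP. Free RNA, estimated at 48.9% and 5.27% of UMIs, is not excluded as a source of the enzyme difference or the ACC cells' acinar-like name. With it subtracted the log2 ratio of enzyme sums was 3.97 (main 3.80). Of the ACC cells 31 clustered with normal acinar-like ones, and their part of the sum was not tested. Summed over the list, squamous and basal genes had 63.6 CPM (95% counting interval 53.4 to 75.2) in the ACC, 2489.7 (2410.2 to 2571) in the ASCP, 1118 in Mixed tumour 1 and 455 in Mixed tumour 2. All 19 members were higher in the ASCP than the ACC tumour. Digestive enzymes had 70482 (70128 to 70838), 5062 (4948 to 5177), 28442 and 11996 CPM in the same order, and 28 of 28 were higher in the ACC tumour. Duct and metaplasia genes had 866, 6229, 10523 and 18654 CPM, with 19 of 22 higher in the ASCP tumour, and gastric genes 235, 701, 2279 and 8158 CPM. MYC targets had 13512, 16947, 15297 and 17480.1 CPM, and cell cycle genes 1315, 2755, 1675 and 1715. Within acinar-like cells alone the enzyme sum was 30365 CPM in the ASCP tumour and the squamous sum 263 CPM.

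Of the genes higher in the ACC tumour, Zg16 (ENSMUSG00000049350, chromosome 7, 127050156 to 127087328), a zymogen granule lectin, had 2499 CPM there, 7.4 in the ASCP, and 358 and 68.0 in the Mixed tumours, 338-fold (189 to 677). The carboxypeptidase Cpb1 was 154-fold (119.8 to 202), the elastase Cela1 78.6-fold (62.5 to 100.2), Sycn 59.6-fold (39.6 to 94.2), Ctrl 57.9-fold (37.3 to 95), Try5 34.7-fold (29.1 to 41.7) and Pnlip at least 292-fold higher. Chga, a granule protein of endocrine cells, was 216-fold (131 to 386), Vtn 1069.7-fold (192 to 42277) and the cardiac troponin gene Tnni3 251-fold (69.2 to 2077) higher. Of the genes higher in the ASCP tumour, S100a6 was 371-fold (232 to 638) higher, the basal keratins Krt5 (ENSMUSG00000061527, chromosome 15, 101707070 to 101712898) at least 453-fold and Krt14 1424-fold (255 to 56281), Ly6d at least 245-fold and the duct keratin Krt7 213-fold (82.7 to 784). The growth factor gene Ptn was at least 708-fold higher, the WNT pathway gene Nkd1 at least 401-fold, the transcription factor gene Sox11 at least 358-fold, Tff1 at least 283-fold and Igfbpl1 384-fold (106 to 3183). Before any scaling Msi2 had 58.0 CPM in the ACC, 88.1 in the ASCP, and 42.1 and 45.1 in the Mixed tumours, and Myc 46.0, 49.1, 66.5 and 56.5.

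**Figure D5:**
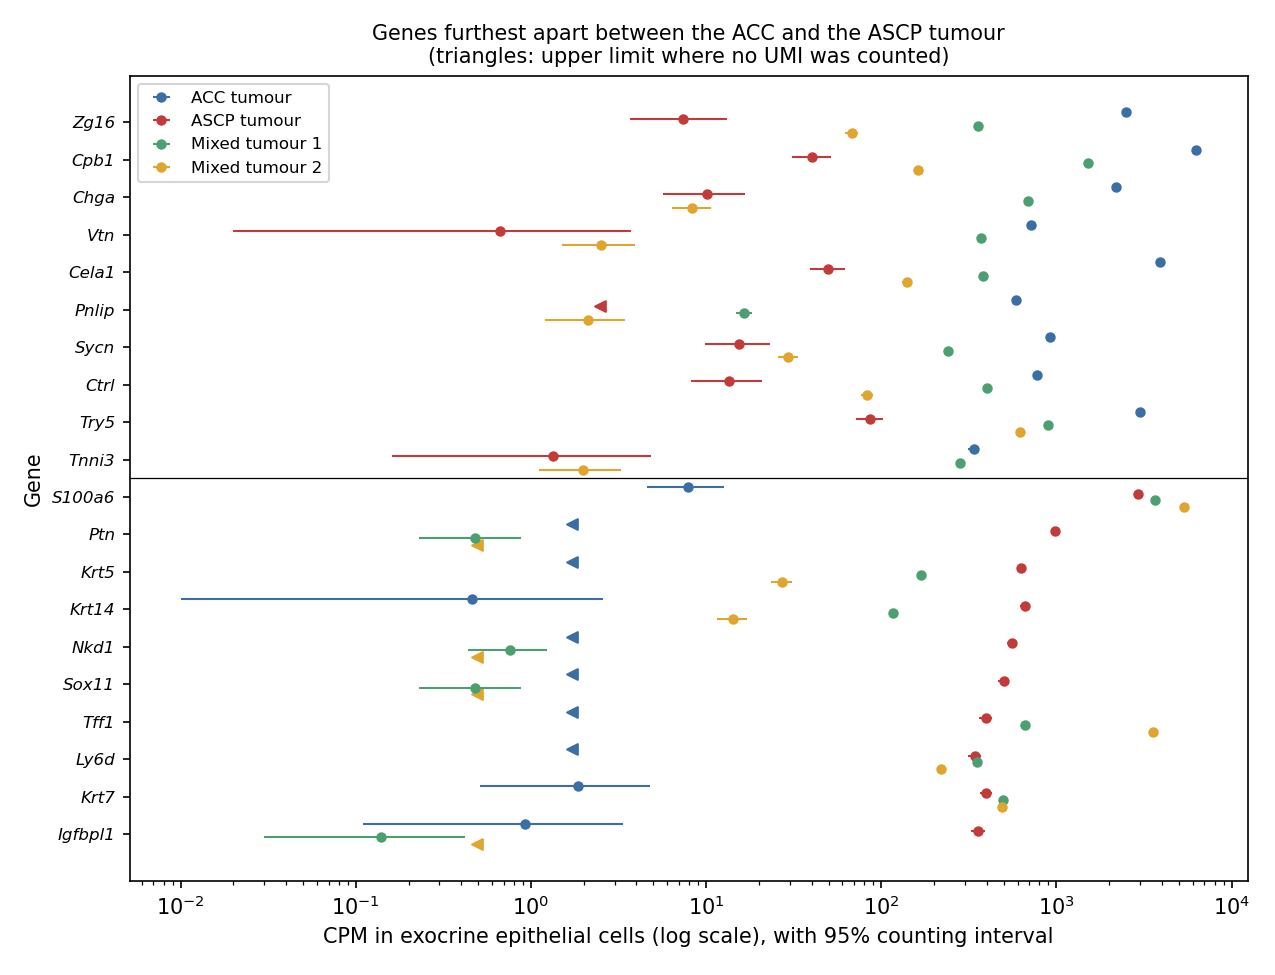
Raw CPM in exocrine epithelial cells (log axis) of the 20 genes named between the ACC and ASCP tumours, 1 point per tumour. Zg16 lies at 2499 CPM in the ACC and 7.4 in the ASCP tumour, and Krt5 at 0 and 631, with the Mixed tumours at 169 and 26.97.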

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

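The tests for cells joined to acinar-like cells and for free RNA in the ACC tumour alone and the other splits of the samples were chosen after seeing the results. In each group of 4 tumours, a sample was singled out where its gap to the nearest of the others, over the whole range, was above the 95% limit of Dixon's test. Of 121 groups of 4 tumours tested 19 were singled out, and chance does so in about 1 in 20 groups. In 5 of them the other 3 tumours were at 0, which fixes the outcome, and without these 14 of 116 were singled out.

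By cell class, the acinar-like share of the ACC tumour was 81.7% against 10.4% to 21.1% in the others. The squamous-like share of the ASCP tumour was 9.69% against 0% to 0.621%. Mixed tumour 1 stood apart in macrophage-like cells (44.2% against 0.142% to 6.47%), fibroblast-like cells (5.71% against 0% to 0.041%), neutrophil-like cells (8.11% against 0%, fixed by the zeros) and median UMIs per cell (11380.0 against 1165.5 to 2700.0).

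Of the genes tested, several stood apart in normalised CPM in acinar-like cells of the ACC tumour. Msi2 had 47.0 CPM there against 21.4 to 24.5, Try10 76.3 against 35.7 to 40.95, Cdkn1a 19.2 against 111 to 129 and Tdh 6.39 against 29.2 to 30.96. Ins2 had 1.88 CPM against 0 to 0.32, and Ins1 and Hbb-bs each 0.38 against 0, which is 1 UMI each. Perp had 76.5 CPM in Mixed tumour 2 against 45.9 to 48.4. Over exocrine epithelial cells, Sparc had 72.9 CPM in the ASCP tumour against 0.74 to 12.4, and Hba-a2 9.18 against 0 to 0.05. H2-K1 had 578 CPM in the ACC tumour against 182 to 247, and Ins1 and Hbb-bs each 0.56 against 0, the same 1 UMI each. Outside the comparisons, 77.2% of the called barcodes of the ACC tumour held under 300 genes, against 26.1% and 26.9% in the normal samples, 2.03% to 3.79% in the pre-cancer samples and 8.79%, 4.80% and 5.95% in the ASCP tumour and Mixed tumours 1 and 2.

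Xist was abundant in both normal samples and near 0 in the pre-cancer samples. In exocrine epithelial cells it had 1068 and 1138 CPM in normal samples and 0.11 to 0.24 in pre-cancer samples, while Y-linked genes had at most 0.03 CPM in normal and at least 60.44 CPM in pre-cancer samples. Loss of Xist in female animals is argued against by these Y-linked counts, whose lowest 95% bound was 56.24 CPM. Female normal and male pre-cancer animals would give these counts. The labels give no sex. Line, time and possibly a reporter sort differ along the same line, so these and sex stay open for other genes.

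Digestive enzymes were lower and MYC targets higher in pre-cancer than in normal acinar-like cells. Enzyme genes taking most of the counts of normal cells is argued against as the whole cause, since MYC target UMIs per cell without scaling were 3.84 times as high in the lowest pre-cancer sample as in the highest normal sample. For the enzymes, free RNA in the droplets of the normal samples is argued against by their share of UMIs, which in acinar-like cells was at least 1.393 times that in empty droplets. In pre-cancer samples 1 to 3 it was 1.061, 0.652 and 0.649 times that level, with free RNA estimated at 87.3%, 49.4% and 53.6% of UMIs from 8, 4 and 47 cells, so free RNA stays open as a source of the enzyme UMIs there and of the naming of these cells as acinar-like. Expression of MycT58A may underlie the pattern as a hypothesis, untested here since line, time and possibly a reporter sort differ together between the groups.

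Stromal and immune transcripts were higher in acinar-like cells of the tumours as a group, with 0 UMIs of the tested genes in the ASCP tumour. In the ACC tumour free RNA as the whole source of the immune ones is argued against, since they stood at 1.474 times the level in empty droplets (95% interval 1.131 to 1.918), with 63 of 112 UMIs in 9 of 1653 cells, while the stromal ones stood at 0.601 times (0.465 to 0.772) and free RNA stays open for them. Over the 4 tumours free RNA may account for a part: 87.0% of the counted values (20 of 23) lay at or below that level, short of the 90% asked for, and the 3 above it were all in the ACC tumour, whose 9 values ran from 45.9% to 272% of it. In Mixed tumour 1 they were 0.56% to 2.05% of it. There the 5% of cells with most such UMIs held 0.82 times what depth predicts (18.9% against 23.1%, SD 0.8). In the ACC tumour they held 1.65 times (75.8% against 46.1%, SD 1.7), between the bounds set at 1.2 and 2. Free RNA need not follow a cell's depth, so joined cells stay open in both. Expression by the acinar-like cells themselves was not tested.

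For tumours against pre-cancer in acinar-like cells, 2.0 of the 35 splits of the 7 samples gave as many genes as the real one, itself included. Chance cannot be excluded there, with 476 genes in the real split and 928 in the highest other, which set Mixed tumour 2 and the 3 pre-cancer samples against the rest. In exocrine epithelial cells 1 of 35 did, the real one, with 1691 genes against 1200 in the next split, the ACC tumour with the pre-cancer samples. That share, 0.0286, is the least 35 splits can give, and the count was 33 to 46 without 1 pre-cancer sample. Splits with pre-cancer samples on both sides gave 0, so this test cannot exclude chance.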

How the results depend on the processing

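The alternatives chosen after seeing the data are named above. The planned comparisons left out had no pre-cancer sample with 20 cells of the class. Of 1437 values of the 68 named genes for pre-cancer against normal in acinar-like cells, 1311 kept direction and side of the threshold, 105 were weaker, 8 stronger and 13 opposite. Among exocrine epithelial cells these counts were 1564, 51, 1 and 12 of 1628. For tumours against pre-cancer they were 950, 225, 6 and 12 of 1193 in acinar-like and 1131, 330, 2 and 21 of 1484 in exocrine epithelial cells. The cause of a change was not tested unless the alternative itself uses fewer samples or counts. Where 1 sample was left on a side, it was assumed to vary like the other groups.

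For pre-cancer against normal in acinar-like cells (4881 genes), leaving out 1 sample gave 3197 to 3916 genes, the lowest without normal sample 2. Subtracting ambient RNA gave 1148, thinning to the smallest sample 880 and total UMIs as the scale 9575. For exocrine epithelial cells (8950 genes) leaving out 1 sample gave 7318 to 7845 and subtracting ambient RNA 3258. For tumours against pre-cancer in acinar-like cells (476 genes), leaving out 1 sample gave 3 to 1661, the lowest without pre-cancer sample 1 and the highest without Mixed tumour 2. The DESeq2 Wald test gave 871, no filter 1103, naming cells by their own marker score 817, only cells differing from the ambient profile 150 and thinning 8. Only the samples of the 2 sides gave 220 and only the Mixed tumours 752. Subtracting ambient RNA gave 0 with edgeR. For exocrine epithelial cells (1691 genes), leaving out 1 sample gave 33 to 2669, the lowest without pre-cancer sample 3 and the highest without the ACC tumour. The Wald test gave 3426, no filter 998, subtracting ambient RNA 26, thinning 193, only the 2 sides 1047 and only the Mixed tumours 3431.

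With a replicate block on the replicate numbers, 2596 genes passed for Mixed tumours against pre-cancer in exocrine epithelial cells and 357 in acinar-like cells, and 9122 and 4958 for pre-cancer against normal. The numbers are shared by 2 pairs only, whose deviations correlated at 0.021 to 0.341, and they were not taken to pair the samples. Under the block Hbb-bs was at -3.81 and H2-K1 and Jun in tumours at -0.083 and 0.328, all in exocrine epithelial cells.

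In acinar-like cells, pre-cancer against normal, total UMIs as the scale put Myc at 1.26 (1.265), Msi2 at 1.42, Rpl41 at 1.59, Tapbp at 1.29, H2-K1 at 1.49, Trp53inp1 at 0.61 and Hbb-bs at 0.28, each the opposite of its main value. Under it the acinar transcription factors and the unfolded protein response had list medians of 0.28 and 0.57, the only lists past camera to change sign there. Leaving out 1 sample put Hbb-bs between -6.67 (without pre-cancer sample 3) and 6.94 (without normal sample 1) and Perp between -0.16 (without normal sample 2) and 0.78 (without normal sample 1). Hbb-bs was at 6.56 (6.555) with ambient RNA subtracted, and Perp at -0.19. Ier3 was at -0.71 with cells named by their own score and -0.27 with the low-UMI enzyme cluster included. Over exocrine epithelial cells Hbb-bs was at -5.50 with cells named by their own score, -0.004 and -0.27 with total UMIs as the scale with and without enzymes, -4.19 without pre-cancer sample 3, -0.77 without normal sample 2 and at its highest, 5.85, without normal sample 1. Hba-a2 was at 3.28 with ambient RNA subtracted and between -5.78 (without pre-cancer sample 3) and 2.74 (without normal sample 1) on leaving out 1 sample, Prss1 at -8.03 with ambient RNA subtracted, and Myc at 0.039 after thinning, 0.10 without pre-cancer sample 2 and 0.81 without normal sample 1.

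For tumours against pre-cancer in acinar-like cells, subtracting ambient RNA put Try4 at 1.39, Bst2 at 0.045 and Msi2 at -0.085. Msi2 was at -0.006 with only the Mixed tumours, and leaving out 1 sample put it between -0.021 (without the ACC tumour) and 0.55 (0.551, without pre-cancer sample 1). Rpl13 was at -0.056 without the ACC tumour. Sfn was at -1.21 and Bax at -0.15 with cells named by their own score, and at -0.25 and -0.215 without Mixed tumour 2, with highs of 1.028 and 0.391 without the ACC tumour. Jun was between -0.002 (without Mixed tumour 1) and 0.29 (without the ACC tumour), and Ins2 between -4.05 and 0.014 on leaving out the ACC tumour and Mixed tumour 1. Over exocrine epithelial cells Jun, near 0 throughout, was at 0.022 with DESeq2 size factors, 0.023 by the Wald test, 0.064 at most 10% mitochondrial UMIs, 0.157 by the cells' own score and 0.001 with ambient RNA subtracted. It was at 0.166 with only cells differing from the ambient profile, 0.155 after thinning, 0.043 with only the 2 sides and 0.223 with only the Mixed tumours, and at 0.052, 0.095 and 0.065 without the ACC tumour, the ASCP tumour and pre-cancer sample 3. Subtracting ambient RNA put Try4 at 0.34 and Hes1 at 0.197, and H2-K1 was at -0.037 with only the Mixed tumours. Without the ACC tumour Rpl13 was at -0.041, Hes1 at 0.126 and H2-K1 at -0.141, and without the ASCP tumour Hes1 and H2-K1 were at -0.675 and 0.54. Hes1 was at 0.036 without Mixed tumour 2.

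Of the lists past camera (9 and 10 in acinar-like cells, 10 and 11 in exocrine epithelial cells, in each case for pre-cancer first), an estimated correlation left 0, 0, 1 and 0, and fry gave 15, 0, 11 and 5. The unnamed epithelial share, 34.6 points higher in tumours than in pre-cancer, was at -4.94 with cells named by their own score. Under the same naming the acinar-like share differed by 26.6 points (main 89.6, and 71.3 with the low-UMI enzyme cluster included) and the ductal-like share by -31.0 (main -59.4, and -53.3 without the ciliary cluster) between pre-cancer and normal, and the acinar-like and squamous-like shares by -38.4 (main -65.6) and 6.29 (main 2.66) between tumours and pre-cancer. Leaving out 1 sample gave 23.03 (without the ASCP tumour) to 46.1 points for the unnamed epithelial share, 86.4 to 92.8 and -66.2 to -52.7 for the acinar-like and ductal-like shares of pre-cancer against normal, and -81.8 to -58.0 for the acinar-like share in tumours. It gave 0.317 (without the ASCP tumour) to 3.55 for the squamous-like and 2.25 (without Mixed tumour 1) to 16.95 for the macrophage-like share in tumours. Between the ACC and ASCP tumours, the log2 ratio of the squamous sum (-5.29) was -5.82 by the cells' own score, -4.97 with ambient RNA subtracted and -5.63 with only cells differing from the ambient profile. That of digestive enzymes (3.80) was 4.28 at most 10% mitochondrial UMIs, 3.84 at 1000 UMIs or more, 3.91 by the cells' own score, 3.97 with ambient RNA subtracted and 3.36 with only cells differing from the ambient profile. The duct ratio (-2.85) was -2.76, -3.18, -2.72 and -3.055 under the same alternatives save 1000 UMIs.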

Other observations

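No test was run on the cluster genes below, chosen after their values were seen.

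The ASCP tumour held 462 of the 464 cells of a group whose 10 leading genes include Sox11 (688 CPM), Sox2 (379), Ptn (1354), Nkd1 (771), Axin2 (304) and Wif1 (266). A second group was led by genes such as Tff1 (3239 CPM), Lgals4 (1728), Spink4 (847) and Ctse (349), and held 1490 cells of Mixed tumour 2, 185 of Mixed tumour 1 and 24 of the ASCP tumour.

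Most acinar-like cells of the ACC tumour, 1609 of 1653, lay in 1 group with Vtn (752 CPM), Tff3 (422) and Tnni3 (358), and no enzyme gene, among its leading genes. It also held 37 cells of pre-cancer sample 3, 36 of Mixed tumour 1, 7 of Mixed tumour 2 and 1 of normal sample 1, and 0 of their barcodes were shared with ACC cells. Another 31 ACC cells lay with the normal acinar-like cells. Of the 1653, 25 held Xist without Y-linked UMIs and 265 the reverse. Mixed tumour 1 held 175 of the 176 cells of a group at a median of 39359.5 UMIs with Vtn (1047 CPM), H19 (812), Tnni3 (791) and Peg10 (461).

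Most ductal-like cells of the normal samples lay in 2 groups that each held mainly 1 of them, with 48 and 2752 and with 1048 and 20 cells of samples 1 and 2, while 2 smaller groups had 227 and 48 and 6 and 10 cells. A group at low UMIs with Gdf15 and Cdkn1a among its leading genes held 442 cells of Mixed tumour 2, 112 of Mixed tumour 1, 72 of the ASCP tumour and 69, 51 and 47 of the pre-cancer samples. Of the tumours, Y-linked genes had 136, 95.5, 77.2 and 0.13 CPM and Xist 20.4, 0, 0.29 and 549 CPM in the ACC, the ASCP, Mixed tumour 1 and Mixed tumour 2. In the normal samples Msi2 had 252 and 126 CPM in ductal-like cells and 183 and 93.1 in endocrine-like cells.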
